A study of Mus musculus with 24 samples.

How the data were processed

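The 24 samples were cultures of hippocampal neurons from mouse embryos of embryonic day 16. Per the labels, the cultures were infected on day 3 in vitro with lentivirus expressing a short hairpin RNA, either a control hairpin or a hairpin against Npas4, and were depolarized with KCl on day 8 in vitro for 0, 1, 3 or 6 hr. The labels give the KCl concentration as 50 mM in the description of the series and as 55 mM in that of the samples. Total RNA (200 ng) was turned into biotin-labelled cRNA and hybridized to Affymetrix expression arrays, per the labels' protocols. Groups were taken from the sample titles, which give 8 groups of 3 arrays. The labels state 3 independent experiments, and replicate numbers run from 1 to 3 in each group.

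The deposited table held a linear intensity for each of 45101 probe sets on each array. Per the submitters' processing notes, MAS5 was used for 12 of the 24 arrays, 11 of the 12 control arrays and 1 of the 12 Npas4 RNAi arrays. For the other arrays the software was not given in the sources used here. The trimmed mean of the deposited intensity, leaving out 2% at each end, was 500.003 on every array, so that all 24 arrays carried the same global scaling. Median intensities ranged from 72.3 to 90.5 and the 40th percentile, which served as a measure of background, from 41.6 to 55.5. No pair of arrays held identical values, and the highest correlation between the log2 values of a pair of arrays was 0.944. For arrays, the number of samples limits the precision.

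Intensities were scaled to a trimmed mean of 500, raised by an offset of 32 and transformed to log2. A log2 difference on this scale understates the change of genes with intensities near or under the offset. The 64 Affymetrix control probe sets were left out of the tests. Gene names came from the platform annotation table given with the data. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none there, and 34754 of those with 1 symbol were found by Entrez ID in a RefSeq gene table, which changed 0 symbols. No gene was named from a probe set with several symbols. Probe sets above their array's 40th percentile on at least 3 arrays were kept, which left 32431. Each gene was represented by the probe set with the highest mean log2 value among those kept, which gave 14754 genes, of which 7150 had more than 1 probe set. Among the named genes with a called difference, 561 values came from other probe sets of the same gene. Of these, 43 had the opposite sign, and 1 of the 43 was itself called, for Dnajb1 after 6 hr of KCl.

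Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 8 groups and no covariate, over all 24 arrays, so that the groups shared an estimate of the spread. P-values were two-sided and were adjusted with the Benjamini-Hochberg method over the 14754 genes, and a gene was called at an adjusted p under 0.05. The contrasts were 1, 3 and 6 hr of KCl against 0 hr with the control hairpin, the Npas4 hairpin against the control hairpin at each time and over the mean of the 4 times, and the difference in response between hairpins at 1, 3 and 6 hr, which is the interaction term. Standard errors are those of limma. A set of 27 gene lists, fixed before the data were examined, was tested with camera at a preset correlation of 0.01 and adjusted over the 27 lists within a contrast. Camera with an estimated correlation and fry were the alternatives. A list needed at least 5 tested members. Lists could share genes, so that their calls are not separate. Arc was in the effector list and among the described Npas4 targets, and Nr4a1 was among the immediate early factors and the targets. Whether genes were described as Npas4 targets on the basis of these same data was not checked. Called members were counted after adjustment over all genes and after adjustment over the list alone. Responsive genes were those called with at least a 2-fold change in the mean response of both hairpins, a contrast that shares no noise with the hairpin contrast in this balanced design. Their hairpin difference was a planned test, whereas the test of their difference in response was added after the data had been seen. P-values of both were adjusted over the 10 tests together.

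The rule for named genes was also fixed before the data were examined. It took Npas4 in every group, then up to 12 genes with the largest rise and up to 12 with the largest fall among the called genes, for single times those whose 3 values per group did not overlap. Chance alone keeps the groups of a gene from overlapping in 10% of cases with 3 against 3. Within each list it took up to 4 called members with the largest difference, or up to 2 members as values where none was called. Where a contrast had no call, it took the 5 genes with the smallest unadjusted p.

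The model was tested on simulated data with the means and spreads of the 14754 genes. For 6 hr against 0 hr of KCl, 42% of genes changed 1.5-fold were recovered and 86% of those changed 2-fold. For the hairpins at 0 hr these shares were 48% and 84%, for the mean of the 4 times 92% and 98%, and for the difference in response at 6 hr 28% and 60%. Of 100 unchanged lists, camera called 3 or 4 at an unadjusted p under 0.05 and fry 3 to 6. With no hairpin effect in 20 simulated runs, the median difference in response of genes chosen as responsive at 6 hr lay between -0.043 and 0.026. The simulated genes varied independently of each other and carried no effect of the replicate. The values for lists and medians therefore do not cover genes that vary together, and correlated genes would widen both.

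The replicate numbers were checked for pairing through the correlation of deviations from the group means. All 3 same-numbered pairs correlated above 0.1 in 2 of the 7 compared pairs of groups, namely control 0 hr with control 1 hr (lowest correlation 0.178) and the hairpins at 6 hr (lowest 0.114). With the replicate number as a block, these comparisons had 75 and 2302 called genes, against 53 and 1582 without it. The main model had no block.

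Alternatives covered the log2 offset, the scaling between arrays, the filter, the choice of probe set, the replicate block, the variance model, array weights, a fold threshold, a fit with only the compared arrays and leaving out each array. The 3' to 5' ratios of the Gapdh and actin control probe sets served as measures of RNA quality and were compared between hairpins with a permutation test of 100000 resamples in scipy 1.17.1. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. Probe sets with no gene symbol and the hairpin sequences were not used here.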

Results

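Transcript levels were measured in cultured mouse hippocampal neurons that carried either a control hairpin or a hairpin against Npas4, a neuronal transcription factor that is induced by membrane depolarization. Neurons were depolarized with KCl for 0, 1, 3 or 6 hr, and each of the 8 groups had 3 arrays from 3 independent experiments. The first 2 principal components held 25.8% and 14.9% of the variance. All differences below are on the log2 scale with their standard error and 3 arrays per group, and a gene is said to have risen or fallen only where limma gave an adjusted p under 0.05.

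The targeted gene was examined first. With the control hairpin, the mean intensity of Npas4 was 274 at 0 hr, 9770 at 1 hr, 13079 at 3 hr and 14587 at 6 hr of KCl (n = 3 each). With the Npas4 hairpin it was 44.6, 2552, 2214 and 1872 at the same times. The Npas4 hairpin left 26.1% of the control level at 1 hr, 16.9% at 3 hr and 12.8% at 6 hr. At 0 hr its mean of 44.6 (19.2 to 74.2 on 3 arrays) lay in the background of 41.6 to 55.5, so that the share of 16.3% and any rise from that level are not exact. The difference was -2.00 ± 0.23 at 0 hr (adjusted p = 2.76e-05) and -2.95 ± 0.23 at 6 hr (adjusted p = 1.74e-07). Npas4 transcript still rose in neurons with the Npas4 hairpin, by 5.13 ± 0.23 at 1 hr and 4.69 ± 0.23 at 6 hr. Its fold response did not pass the test of a difference between hairpins at 1 hr (0.08 ± 0.33), 3 hr (-0.55 ± 0.33) or 6 hr (-0.95 ± 0.33, adjusted p = 0.598).

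**Figure D1:**
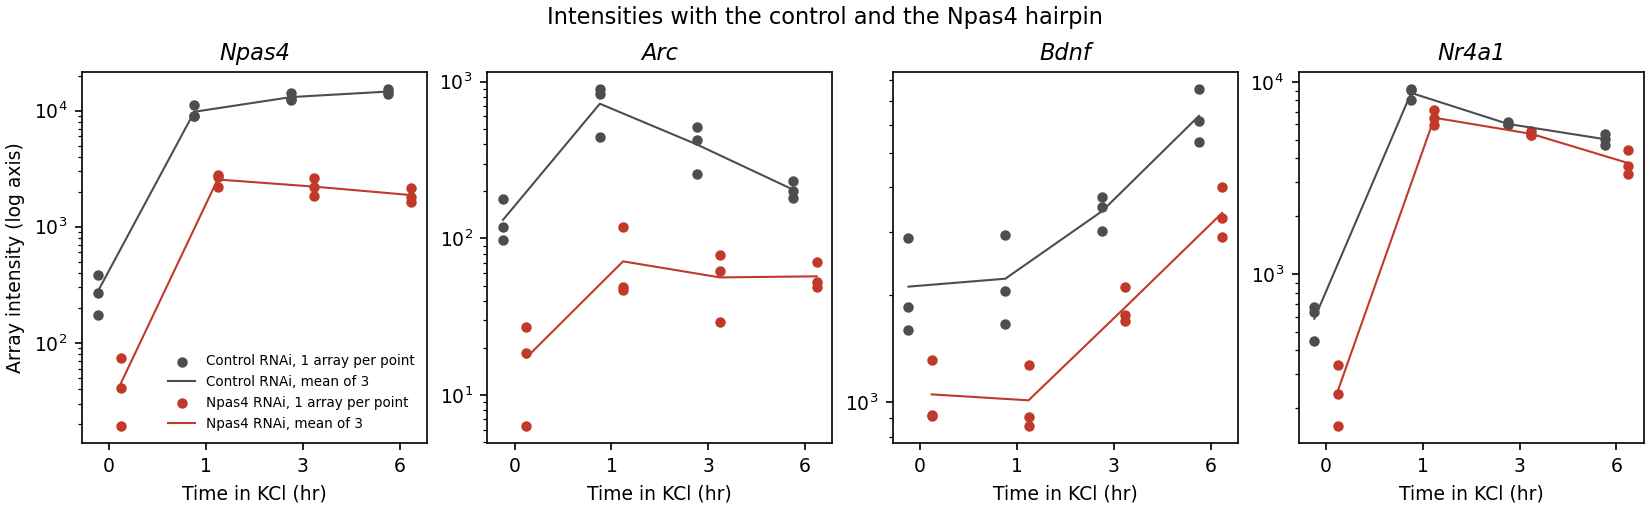
Array intensity on a log axis against hours in KCl for Npas4, Arc, Bdnf and Nr4a1, with a point for each array, lines through the mean of 3 arrays, grey for the control hairpin and red for the Npas4 hairpin. Npas4 went from 274 to 14587 over 6 hr with the control hairpin and from 44.6 to 1872 with the Npas4 hairpin.

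The comparison of 1 hr with 0 hr of KCl in control neurons asked which genes respond first to depolarization. The largest rises were those of Npas4 (5.05 ± 0.23), of the AP-1 transcription factor genes Fosb (4.30 ± 0.17), Fos (3.61 ± 0.18) and Junb (3.43 ± 0.14), and of Nr4a1, an orphan nuclear receptor (3.85 ± 0.17). Their adjusted p-values lay between 1.04e-11 and 1.28e-10. Klf4 rose by 3.32 ± 0.19, Ier2 by 2.97 ± 0.15, Ccn1 by 2.40 ± 0.19, Egr2 by 2.28 ± 0.22 and Nr4a2 by 2.13 ± 0.17. Arc, which encodes a postsynaptic protein that regulates AMPA receptor trafficking, rose by 2.18 ± 0.30 (adjusted p = 0.000537). The genes that fell included Hes5, a transcriptional repressor (-1.97 ± 0.21), Id3, an inhibitor of bHLH factors (-1.75 ± 0.26), and Nrarp (-0.86 ± 0.15). In all, 53 genes were called, 42 higher and 11 lower, of which 32 changed at least 2-fold.

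Among the 21 immediate early transcription factors, 13 rose at 1 hr, or 18 when adjusted over the list alone, and camera called the list (adjusted p = 3.25e-90, and adjusted p = 4.48e-07 with an estimated correlation). Of 29 activity-regulated effector genes 3 rose, or 4 adjusted over the list alone, among them Gadd45b (1.41 ± 0.22) and Gadd45g (1.16 ± 0.13), which encode stress-inducible proteins. Camera called the effector list (adjusted p = 1.96e-06), but not with an estimated correlation (adjusted p = 0.113 with an estimated correlation). Of 12 feedback regulators of MAPK signalling Dusp1, a MAPK phosphatase, rose by 2.65 ± 0.11, and 2 rose when adjusted over the list alone (camera adjusted p = 0.00214, and adjusted p = 0.173 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress response 2 rose, also adjusted over the list alone, namely Ppp1r15a (0.93 ± 0.10) and Atf4 (0.58 ± 0.10), with a camera adjusted p = 0.00214 (adjusted p = 0.173 with an estimated correlation). Of 18 astrocyte markers, Hes5 and Id3 fell, also adjusted over the list alone, and the median of the list was -0.03 (camera adjusted p = 0.151, and 0.0463 after quantile normalization). Of 14 genes described as Npas4 targets 2 rose, also adjusted over the list alone (camera adjusted p = 0.000386, and adjusted p = 0.113 with an estimated correlation). None of 12 microglia markers was called by limma, but all 12 values were above 0 with a median of 0.27 (camera adjusted p = 0.00646, and adjusted p = 0.457 with an estimated correlation). A fit on only the 6 arrays compared called 23 genes, and a fit on all probe sets called 86 probe sets.

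After 3 hr of KCl, Fosb (5.35 ± 0.17), Junb (4.13 ± 0.14), Klf4 (3.86 ± 0.19), Fos (3.81 ± 0.18) and Nr4a1 (3.32 ± 0.17) were above their level at 0 hr, with adjusted p-values between 3.23e-13 and 1.63e-10. Maff, a small Maf transcription factor gene, rose by 2.79 ± 0.33 and Fbxo33, which encodes an F-box protein, by 2.47 ± 0.18. The largest falls with non-overlapping groups included those of the zinc finger genes Zfp688 (-1.66 ± 0.46) and Zfp87 (-1.42 ± 0.15), of Thrsp (-1.34 ± 0.12) and of Slc30a1, a zinc exporter (-1.26 ± 0.09). In all, 1178 genes were called, 402 higher and 776 lower, and 131 of them changed at least 2-fold. The share called higher was 34.1%, and 43.1% after quantile normalization, so that the size of the excess of falls depends on the scaling.

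At 3 hr 19 of the 21 immediate early transcription factors rose, also when adjusted over the list alone. The immediate early list had a camera adjusted p = 9.62e-52, and adjusted p = 2.03e-05 with an estimated correlation. Of the 29 effector genes 8 rose, or 14 adjusted over the list alone, with Gadd45b at 1.85 ± 0.22 and Sertad1 at 1.60 ± 0.20. The effector list had a camera adjusted p = 9.06e-09, and adjusted p = 0.0454 with an estimated correlation. Of the 12 MAPK feedback regulators 3 rose, Dusp1 (2.78 ± 0.11), Errfi1 (1.81 ± 0.12) and Dusp16 (0.89 ± 0.14), and 5 rose and 1 fell when adjusted over the list alone. The MAPK list had a camera adjusted p = 1.59e-05, and adjusted p = 0.0454 with an estimated correlation. Of the 18 stress response genes 5 rose and 1 fell, also adjusted over the list alone, with Ppp1r15a at 1.82 ± 0.10, Atf4 at 1.07 ± 0.10 and Herpud1, an endoplasmic reticulum protein of degradation, at 0.96 ± 0.13. The stress response list had a camera adjusted p = 0.000118, and adjusted p = 0.0647 with an estimated correlation. Of 27 voltage-gated ion channel genes 8 fell and 0 rose by limma, or 9 fell adjusted over the list alone, with the potassium channel genes Kcna1 at -0.99 ± 0.22 and Kcnc1 at -0.73 ± 0.15. The ion channel list had a camera adjusted p = 0.000118, and adjusted p = 0.0811 with an estimated correlation. Of 16 genes of GABAergic transmission 2 fell, Gad2, which encodes a GABA-synthesizing enzyme (-0.78 ± 0.15), and Gabrb2, a GABA-A receptor subunit (-0.32 ± 0.09), and 4 fell adjusted over the list alone. The GABAergic list had a camera adjusted p = 0.00342, and adjusted p = 0.271 with an estimated correlation. Of 14 interneuron markers 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.518 with an estimated correlation). Of 19 cell cycle genes 2 rose, Cdk1 (0.48 ± 0.13) and Pcna (0.34 ± 0.08), or 3 adjusted over the list alone. The cell cycle list had a camera adjusted p = 3.97e-05, and adjusted p = 0.32 with an estimated correlation. Of 14 genes described as Npas4 targets 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.000181, and adjusted p = 0.0647 with an estimated correlation). Of 12 heat shock genes 2 rose, or 2 rose and 1 fell adjusted over the list alone, with Dnajb4 at 1.34 ± 0.11 (camera adjusted p = 0.005, adjusted p = 0.0539 with an estimated correlation, and 0.0564 after quantile normalization). Of 17 hypoxia and glycolysis genes 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.192 with an estimated correlation, and 0.186 after quantile normalization). None of 17 ribosomal protein genes was called by limma, also adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.00269, adjusted p = 0.465 with an estimated correlation, and 0.186 after quantile normalization). The 18 astrocyte markers had a median of 0.01, with Vim rising (0.42 ± 0.06) and Hes5 falling (-1.08 ± 0.21). With only the 6 arrays compared, limma called 377 genes, and 755 were called without replicate 2 of the control neurons at 3 hr.

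After 6 hr of KCl, the largest falls were those of Nxph2 (-2.69 ± 0.26, adjusted p = 3.4e-07), Kif26a (-2.20 ± 0.69), Nxph1 (-2.15 ± 0.20, adjusted p = 2.49e-07), Riox1 (-2.12 ± 0.18) and Chst12 (-2.09 ± 0.21). Nxph1 and Nxph2 encode neurexophilins, which are ligands of neurexins. Gad2 fell by 1.91 ± 0.15 (adjusted p = 4.8e-08), the protocadherin gene Pcdh20 by 1.95 ± 0.10 (adjusted p = 9.57e-11), Slitrk3 by 1.87 ± 0.32 and the potassium channel gene Kcna1 by 1.87 ± 0.22. The largest rises were those of Npas4 (5.63 ± 0.23), Fosb (5.36 ± 0.17), Junb (3.82 ± 0.14) and Fos (3.79 ± 0.18), followed by Klf4 (3.43 ± 0.19), Nr4a2 (3.36 ± 0.17), Maff (3.34 ± 0.33), Nr4a1 (3.05 ± 0.17), Nfil3 (2.99 ± 0.18) and Serpinb2 (2.68 ± 0.22). In all, 4147 genes were called, 1363 higher and 2784 lower, and 545 changed at least 2-fold, 196 higher and 349 lower. The share called higher was 32.9%, and 40.6% after quantile normalization, so that here too the excess of falls depends in size on the scaling.

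At 6 hr 18 of the 21 immediate early transcription factors rose, and 19 rose and 1 fell when adjusted over the list alone. The immediate early list had a camera adjusted p = 3.43e-24, and adjusted p = 0.00188 with an estimated correlation. Among the 29 effector genes 16 rose and 3 fell, or 17 and 5 adjusted over the list alone, with Bdnf, a secreted neurotrophin, at 1.61 ± 0.23 and the prohormone convertase gene Pcsk1 at 1.65 ± 0.20. The effector list had a camera adjusted p = 3.3e-06, and adjusted p = 0.0538 with an estimated correlation. Among the 12 MAPK feedback regulators 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Errfi1 at 2.18 ± 0.12. The MAPK list had a camera adjusted p = 9.22e-05, and adjusted p = 0.052 with an estimated correlation. Of the 18 stress response genes 7 rose and 1 fell, or 10 and 1 adjusted over the list alone, with Ppp1r15a at 2.15 ± 0.10, Herpud1 at 1.70 ± 0.13 and Atf4 at 1.40 ± 0.10. The stress response list had a camera adjusted p = 1.17e-05, and adjusted p = 0.052 with an estimated correlation. Of the 27 ion channel genes 17 fell and 0 rose by limma, also adjusted over the list alone, with Kcnv1 at -1.65 ± 0.21 and Kcnc2 at -1.49 ± 0.18. The ion channel list had a camera adjusted p = 1.17e-05, and adjusted p = 0.052 with an estimated correlation. Of the 16 GABAergic genes 7 fell, or 12 adjusted over the list alone, including the vesicular GABA transporter gene Slc32a1 (-1.51 ± 0.13) and Gad1 (-1.04 ± 0.19). The GABAergic list had a camera adjusted p = 0.000487, and adjusted p = 0.163 with an estimated correlation. Of the 14 genes described as Npas4 targets 6 rose and 2 fell, also adjusted over the list alone. The target list had a camera adjusted p = 0.00565, and adjusted p = 0.163 with an estimated correlation. Of the 14 interneuron markers 9 fell, or 10 adjusted over the list alone, with the transcription factor gene Lhx6 at -1.71 ± 0.14 and Dlx5 at -1.49 ± 0.20. The interneuron list had a camera adjusted p = 1.54e-05, and adjusted p = 0.163 with an estimated correlation.

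Markers of other cells also moved over these 6 hr. Of the 18 astrocyte markers 4 rose and 1 fell, also adjusted over the list alone, with Gja1 at 0.83 ± 0.13, Vim at 0.73 ± 0.06 and Sox9 at 0.59 ± 0.14 (camera adjusted p = 0.0149, adjusted p = 0.343 with an estimated correlation, and 0.17 after quantile normalization). Of the 12 microglia markers Cd68 rose (0.66 ± 0.19), also adjusted over the list alone, and the median was 0.35 (camera adjusted p = 0.039, adjusted p = 0.343 with an estimated correlation, and 0.0577 after quantile normalization). Of the 19 cell cycle genes 10 rose, also adjusted over the list alone, with Cenpa at 0.64 ± 0.16 and Pcna at 0.54 ± 0.08. The cell cycle list had a camera adjusted p = 2.23e-05, and adjusted p = 0.251 with an estimated correlation. Of 15 markers of hippocampal excitatory neurons 4 fell and 0 rose by limma, and 5 fell and 1 rose adjusted over the list alone, with the calbindin gene Calb1 at -1.51 ± 0.09 and Neurod1 at -1.34 ± 0.22 (camera adjusted p = 0.162). Of 17 general neuron markers 3 fell, among them Nefh (-1.21 ± 0.26), and 2 fell adjusted over the list alone, with a median of -0.0005 (camera adjusted p = 0.703). The 3' to 5' ratio of the actin control probe sets was 1.15 to 1.17 on the control arrays at 6 hr and 1.20 to 1.27 on those at 0 hr. The Gapdh ratio was 0.704 to 0.733 and 0.682 to 0.729 on the same arrays. A fit on only the 6 arrays compared called 2750 genes, and a fit on all probe sets called 7047 probe sets.

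The hairpins were then compared at 0 hr, before any KCl, to ask which genes differ when Npas4 is reduced in unstimulated neurons. The largest rise with the Npas4 hairpin was that of Guk1, which encodes guanylate kinase (2.44 ± 0.10, adjusted p = 1.17e-11). Arc was lower, at -1.72 ± 0.30 (adjusted p = 0.00146). It had a mean intensity of 131 ± 42.7 (SD, n = 3) with the control hairpin and 17.3 ± 10.4 with the Npas4 hairpin, the latter under the background of 41.6 to 55.5. The cyclooxygenase gene Ptgs2 was at -1.94 ± 0.39, the sorting receptor gene Sorcs3 at -1.62 ± 0.14, Rasgrp1, an activator of Ras, at -1.44 ± 0.33, Egr1 at -1.43 ± 0.24, Egr4 at -1.36 ± 0.22 and the neuropeptide precursor gene Vgf at -1.32 ± 0.16. Higher with the Npas4 hairpin were the mitochondrial fission gene Mtfp1 (1.56 ± 0.11), the ubiquitin ligase gene Trim67 (1.62 ± 0.19), the kinesin gene Kif3b (1.39 ± 0.13) and Lypd6 (1.38 ± 0.32). In all, 1130 genes were called, 577 higher and 553 lower, and 77 differed at least 2-fold.

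At 0 hr 9 of the 21 immediate early transcription factors were called lower and 0 higher by limma, or 11 lower adjusted over the list alone. The immediate early list had a camera adjusted p = 4.33e-07, and adjusted p = 0.132 with an estimated correlation. Of the 29 effector genes 13 were lower and 1 higher, or 16 and 1 adjusted over the list alone. The effector list had a camera adjusted p = 5.78e-08, and adjusted p = 0.132 with an estimated correlation. Of the 12 MAPK feedback regulators 3 were lower, Dusp6 (-1.11 ± 0.26), Spry4 (-1.09 ± 0.18) and Dusp4 (-0.94 ± 0.13), while Dusp1 was higher (0.40 ± 0.11), and adjusted over the list alone 5 were lower and 1 higher. The MAPK list had a camera adjusted p = 0.007, and adjusted p = 0.212 with an estimated correlation. Of the 14 genes described as Npas4 targets 6 were lower, or 7 lower and 1 higher adjusted over the list alone, with Nr4a1 at -1.19 ± 0.17 and Bdnf at -0.96 ± 0.23. The target list had a camera adjusted p = 0.000458, and adjusted p = 0.132 with an estimated correlation. Of the 19 cell cycle genes 10 were lower, or 15 adjusted over the list alone, with the replication gene Mcm5 at -0.80 ± 0.16, Top2a at -0.78 ± 0.14 and Mki67, a marker of proliferating cells, at -0.72 ± 0.15. The cell cycle list had a camera adjusted p = 1.6e-10, and adjusted p = 0.186 with an estimated correlation. Of 14 genes of cholesterol synthesis 2 were higher, or 4 adjusted over the list alone (camera adjusted p = 0.00069, and adjusted p = 0.212 with an estimated correlation). The astrocyte marker Aldh1l1 was lower (-0.50 ± 0.10). The Gapdh 3' to 5' ratio was 0.733 to 0.759 on the Npas4 RNAi arrays and 0.682 to 0.729 on the control arrays. The actin ratio was 1.17 to 1.22 and 1.20 to 1.27 on the same arrays. With only the 6 arrays compared, limma called 208 genes, and 654 were called without replicate 3 of the Npas4 RNAi neurons and 661 without replicate 2 of the control neurons.

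After 1 hr of KCl, Arc was lower with the Npas4 hairpin, at -2.88 ± 0.30 (adjusted p = 1.16e-05). Its mean intensity was 71.4 ± 40.6 there and 723 ± 246 with the control hairpin (SD, n = 3 each). The neuropeptide gene Cort was at -1.71 ± 0.39, Sorcs3 at -1.62 ± 0.14, Crhbp, which encodes a binding protein of corticotropin-releasing hormone, at -1.54 ± 0.38, and Egr2 at -1.34 ± 0.22. Guk1 (2.58 ± 0.10), Mtfp1 (1.69 ± 0.11), Trim67 (1.47 ± 0.19) and the lipoprotein lipase gene Lpl (1.31 ± 0.16) were higher. In all, 1045 genes were called, 561 higher and 484 lower, and 71 differed at least 2-fold. Of the 21 immediate early transcription factors 9 were lower, or 11 lower and 1 higher adjusted over the list alone. The immediate early list had a camera adjusted p = 9.95e-07, and adjusted p = 0.0978 with an estimated correlation. Among the 29 effector genes 11 were lower and 0 higher by limma, or 15 and 1 adjusted over the list alone, with Vgf at -1.27 ± 0.16 and Bdnf at -1.09 ± 0.23. The effector list had a camera adjusted p = 1.87e-11, and adjusted p = 0.0434 with an estimated correlation. Of the 19 cell cycle genes 9 were lower, or 17 adjusted over the list alone (camera adjusted p = 2.58e-13, and adjusted p = 0.0978 with an estimated correlation). Among the 12 MAPK feedback regulators 4 were lower, also adjusted over the list alone (camera adjusted p = 0.000579, and adjusted p = 0.0978 with an estimated correlation). Of the 14 described Npas4 targets 4 were lower, or 5 adjusted over the list alone, with Nptx2, a neuronal pentraxin, at -0.90 ± 0.20. The target list had a camera adjusted p = 0.000579, and adjusted p = 0.0978 with an estimated correlation. Of the 18 stress response genes Hsp90b1 was lower (-0.39 ± 0.11), and none adjusted over the list alone. The stress response list had a camera adjusted p = 0.00929, and adjusted p = 0.277 with an estimated correlation. The Gapdh 3' to 5' ratio was 0.726 to 0.785 on the Npas4 RNAi arrays and 0.684 to 0.727 on the control arrays. The actin ratio was 1.14 to 1.22 and 1.19 to 1.23 on the same arrays. A fit on only the 6 arrays compared called 167 genes. The count was 592 without replicate 1 and 543 without replicate 2 of the control neurons, and 664 without replicate 1 of the Npas4 RNAi neurons.

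After 3 hr, Arc (-2.27 ± 0.30), Egr4 (-1.71 ± 0.22), Tlcd4 (-1.69 ± 0.17), Egr2 (-1.57 ± 0.22) and Mreg (-1.55 ± 0.33) were the genes with the largest falls next to Npas4 (-2.56 ± 0.23). Guk1 (2.84 ± 0.10), Mtfp1 (2.20 ± 0.11), Ppp1r3e (1.68 ± 0.23), Cnn1, which encodes the actin-binding protein calponin 1 (1.54 ± 0.16), and the DNA repair gene Xpc (1.45 ± 0.14) were higher. In all, 1483 genes were called, 817 higher and 666 lower, and 104 differed at least 2-fold. The Gapdh 3' to 5' ratio was 0.760 to 0.787 on the Npas4 RNAi arrays at 3 hr and 0.696 to 0.733 on the control arrays. The actin ratio was 1.15 to 1.21 and 1.18 to 1.23 on the same arrays. Of the 21 immediate early transcription factors 9 were lower, or 11 adjusted over the list alone. The immediate early list had a camera adjusted p = 1.46e-06, and adjusted p = 0.113 with an estimated correlation. Of the 29 effector genes 11 were lower, or 12 adjusted over the list alone (camera adjusted p = 1.46e-06, and adjusted p = 0.113 with an estimated correlation). Of the 19 cell cycle genes 14 were lower, or 19 adjusted over the list alone, with Birc5 at -0.87 ± 0.12. The cell cycle list had a camera adjusted p = 1.94e-13, and adjusted p = 0.113 with an estimated correlation. Of the 14 described Npas4 targets 6 were lower, also adjusted over the list alone, with Osgin2 at -0.89 ± 0.14. The target list had a camera adjusted p = 0.000448, and adjusted p = 0.113 with an estimated correlation. Of the 12 MAPK feedback regulators 3 were lower, or 4 adjusted over the list alone, with Spry4 at -1.28 ± 0.18 and Errfi1 at -0.85 ± 0.12. The MAPK list had a camera adjusted p = 0.00326, and adjusted p = 0.149 with an estimated correlation. Of the 14 cholesterol synthesis genes 2 were higher, or 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.448 with an estimated correlation, and 0.0734 after quantile normalization). Of 12 heat shock genes Hsph1 was higher (0.58 ± 0.09), also adjusted over the list alone (camera adjusted p = 0.0398, adjusted p = 0.129 with an estimated correlation, and 0.188 after quantile normalization). With only the 6 arrays compared, limma called 485 genes, and 897 were called without replicate 3 of the Npas4 RNAi neurons and 857 without replicate 2 of the control neurons.

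After 6 hr, the synaptotagmin gene Syt12 (-1.84 ± 0.35), Dsc1 (-1.56 ± 0.19), Tmtc4 (-1.50 ± 0.13), Shisa2 (-1.43 ± 0.16), Rasgrf1 (-1.41 ± 0.23) and Arc (-1.41 ± 0.30) were lower with the Npas4 hairpin, next to Npas4 itself. Guk1 (3.02 ± 0.10, adjusted p = 2.5e-13), Mtfp1 (2.38 ± 0.11), Ppp1r3e (2.03 ± 0.23), Pnma2 (1.95 ± 0.16), Kif3b (1.73 ± 0.13), Cnn1 (1.66 ± 0.16) and the heat shock gene Hspa1a (1.49 ± 0.30) were higher. Bdnf was lower, at -0.90 ± 0.23 (adjusted p = 0.016). Its mean intensity was 3392 ± 563 there and 6343 ± 1111 with the control hairpin (SD, n = 3 each). In all, 1582 genes were called, 929 higher and 653 lower, and 102 differed at least 2-fold. At 6 hr the Gapdh 3' to 5' ratio was 0.774 to 0.798 with the Npas4 hairpin and 0.704 to 0.733 with the control hairpin. The actin ratio was 1.18 to 1.20 and 1.15 to 1.17 on the same arrays. Of the 21 immediate early transcription factors 6 were lower, or 9 adjusted over the list alone (camera adjusted p = 3.28e-05, and adjusted p = 0.173 with an estimated correlation). Among the 29 effector genes 11 were lower and 1 higher, or 13 and 1 adjusted over the list alone. The effector list had a camera adjusted p = 2.43e-06, and adjusted p = 0.109 with an estimated correlation. Of the 14 described Npas4 targets 6 were lower, or 8 adjusted over the list alone, with Osgin2 at -1.29 ± 0.14. The target list had a camera adjusted p = 3.8e-05, and adjusted p = 0.109 with an estimated correlation. Among the 12 MAPK feedback regulators 4 were lower and 1 higher, or 5 and 1 adjusted over the list alone. The MAPK list had a camera adjusted p = 0.00685, and adjusted p = 0.196 with an estimated correlation. Of the 19 cell cycle genes 13 were lower, or 16 adjusted over the list alone (camera adjusted p = 6.58e-13, and adjusted p = 0.109 with an estimated correlation). Of 12 heat shock protein genes 4 were higher, also adjusted over the list alone, with Hspa1b at 0.99 ± 0.22 and Hsph1 at 0.50 ± 0.09 (camera adjusted p = 0.0124, and adjusted p = 0.109 with an estimated correlation). A fit on only the 6 arrays compared called 356 genes, and 982 were called without replicate 2 of the control neurons at 6 hr.

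Over the mean of the 4 times (12 arrays per hairpin), Arc (-2.07 ± 0.15), Sorcs3 (-1.41 ± 0.07), Egr4 (-1.37 ± 0.11), Egr2 (-1.32 ± 0.11), Vgf (-1.05 ± 0.08) and Bdnf (-0.96 ± 0.11) were lower with the Npas4 hairpin, with adjusted p-values between 3.13e-11 and 2.88e-06. Guk1 (2.72 ± 0.05), Mtfp1 (1.96 ± 0.06), Trim67 (1.54 ± 0.09), Kif3b (1.45 ± 0.07) and Lpl (1.36 ± 0.08) were higher. The GABA-A receptor subunit genes Gabrb1 (1.01 ± 0.05) and Gabrb2 (1.00 ± 0.04) were higher, as were the AMPA receptor gene Gria3 (0.82 ± 0.08) and the sodium channel gene Scn3a (1.08 ± 0.09), whereas Kcna1 (-1.18 ± 0.11), the synaptic vesicle gene Sv2b (-1.22 ± 0.11) and the vesicular glutamate transporter gene Slc17a7 (-0.56 ± 0.06) were lower. Dicer1, which encodes an enzyme of RNA interference, was lower, at -0.80 ± 0.06. In all, 4652 genes were called, 2360 higher and 2292 lower, and 69 differed at least 2-fold. The model treated the 12 arrays per hairpin as independent, although the labels state 3 independent experiments. These standard errors and p-values therefore do not measure the spread of the hairpin difference between experiments. A fit on all probe sets called 7869 probe sets.

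All 19 cell cycle genes were lower over the mean of the 4 times, also adjusted over the list alone, with Top2a at -0.74 ± 0.07, Mki67 at -0.74 ± 0.08, Mcm5 at -0.73 ± 0.08 and Birc5 at -0.71 ± 0.06 and a list median of -0.56. The cell cycle list had a camera adjusted p = 1.03e-13, and adjusted p = 0.0952 with an estimated correlation. Of the 29 effector genes 20 were lower and 2 higher, or 23 and 2 adjusted over the list alone (camera adjusted p = 2.42e-09, and adjusted p = 0.0952 with an estimated correlation). Of the 21 immediate early transcription factors 13 were lower and 0 higher by limma, or 15 and 2 adjusted over the list alone (camera adjusted p = 5.09e-07, and adjusted p = 0.0952 with an estimated correlation). Of the 14 described Npas4 targets 9 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.00011, and adjusted p = 0.0952 with an estimated correlation). Of the 12 MAPK feedback regulators 8 were lower and 1 higher, or 9 and 1 adjusted over the list alone, with the phosphatase gene Dusp4 at -0.98 ± 0.06 (camera adjusted p = 0.00191, and adjusted p = 0.123 with an estimated correlation). Of the 14 cholesterol synthesis genes 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone, with the mevalonate pathway genes Mvk at 0.44 ± 0.08 and Mvd at 0.35 ± 0.07 (camera adjusted p = 0.00311, and adjusted p = 0.271 with an estimated correlation). Of the 12 heat shock genes 6 were higher, or 7 adjusted over the list alone (camera adjusted p = 0.0309, adjusted p = 0.109 with an estimated correlation, and 0.119 after quantile normalization). Of the 18 astrocyte markers 1 was higher and 4 lower, also adjusted over the list alone, with Aldoc at 0.25 ± 0.05 and Aldh1l1 at -0.48 ± 0.05, and the list median was 0.05 (camera adjusted p = 0.991). The Gapdh 3' to 5' ratio was 0.766 ± 0.0213 with the Npas4 hairpin and 0.713 ± 0.0198 with the control hairpin (SD, n = 12 each, two-sided permutation p = 6e-05), and the actin ratio was 1.19 ± 0.026 and 1.20 ± 0.0338 (permutation p = 0.256). The permutation treated all arrays as independent, without regard to time or replicate number.

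**Figure D2:**
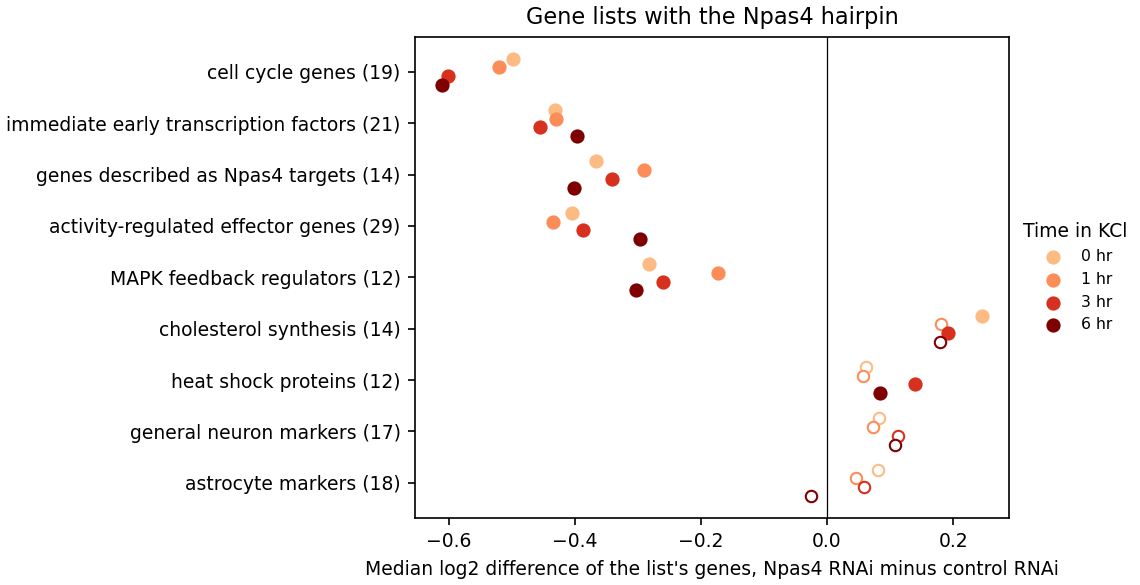
Median log2 difference, Npas4 RNAi minus control RNAi, of the tested genes of 9 lists (number of genes in brackets), by hours in KCl, with filled points where camera gave an adjusted p under 0.05 and open points where it did not. The median of the cell cycle genes lay between -0.50 and -0.61 at the 4 times and that of the immediate early transcription factors between -0.40 and -0.45.

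The hairpin differences at the 4 times, which share no arrays, were set against each other. Across genes, the differences at 0 hr correlated with those at 1 hr (Pearson r = 0.534), 3 hr (r = 0.612) and 6 hr (r = 0.531), where genes are not independent replicates. At both 0 and 6 hr 402 genes were called higher and 291 lower, against 36.3 and 24.5 for independent lists, and 1 was called in opposite directions. The model used the same spread of a gene at all times, so the lists were not independent and these references are likely too low. At all 4 times 523 genes were called, 311 higher and 212 lower in all of them, among 2595 called at any time. The 1045 genes called at 1 hr had a median difference in their direction of 0.45 at 0 hr, 0.51 at 1 hr, 0.47 at 3 hr and 0.44 at 6 hr.

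**Figure D3:**
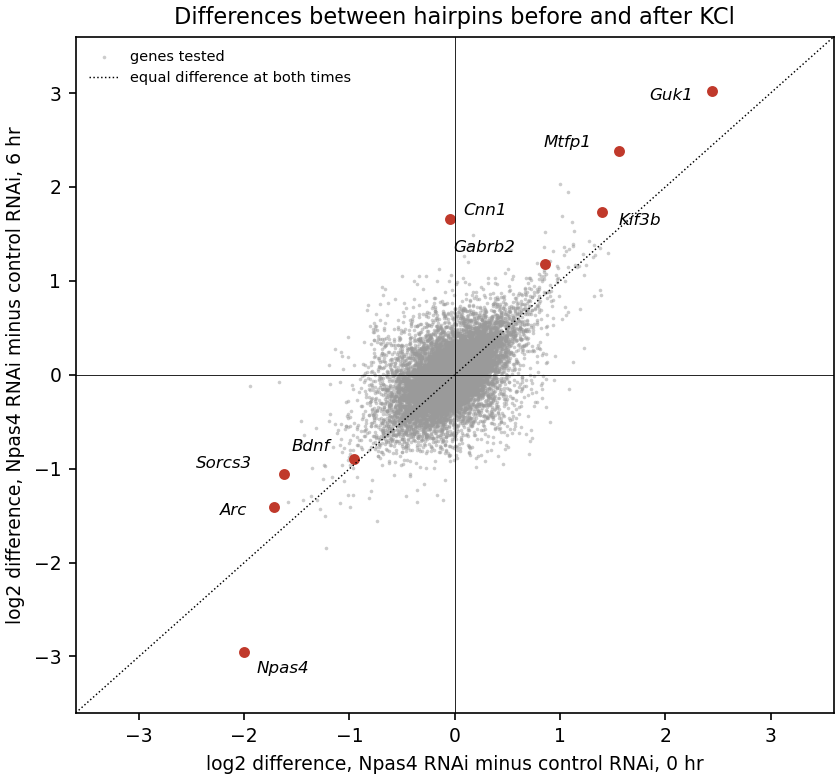
Log2 difference between hairpins (Npas4 RNAi minus control RNAi) at 6 hr against 0 hr of KCl, with a grey point for each of the 14754 genes tested, named genes in red and a dotted line for equal differences. Guk1 lay at 2.44 and 3.02, Arc at -1.72 and -1.41, and Cnn1 differed at 6 hr (1.66).

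The difference in response between hairpins asked which genes respond differently to KCl when Npas4 is reduced. Cnn1 rose more with the Npas4 hairpin, by 1.58 ± 0.23 at 3 hr (adjusted p = 0.0228) and 1.70 ± 0.23 at 6 hr (adjusted p = 0.00799). Its mean intensity at 0, 3 and 6 hr was 12.8, 14.4 and 43.6 with the control hairpin and 11.8, 103 and 209 with the Npas4 hairpin, so that only the latter 2 values lay above the background of 41.6 to 55.5. At 1 hr limma called 0 genes, with 520 at an unadjusted p under 0.05 where 738 would be expected with no effect. The smallest p-values there were those of Crhr2 (1.14 ± 0.22, adjusted p = 0.666), Niban3 (0.93 ± 0.19), Gm9112 (0.90 ± 0.19), Jund (-0.72 ± 0.16) and A930017K11Rik (1.55 ± 0.36). At 3 and 6 hr 1 gene was called at each time, with 495 and 943 genes at an unadjusted p under 0.05. The model had no replicate block, although all 24 arrays correlated best with arrays of their own number. With that block more genes were called at 1 and 6 hr, as listed with the alternatives below. Cnn1 kept its call with it (adjusted p = 0.0243 at 3 hr and 0.0092 at 6 hr). The low counts therefore do not show that the other genes responded alike. The prostaglandin synthesis gene Ptgs2 had differences of 1.55 ± 0.56 at 3 hr and 1.82 ± 0.56 at 6 hr (adjusted p = 0.52 at 6 hr), Nr4a1 of 1.01 ± 0.24 and 0.77 ± 0.24, and the neuropeptide gene Cartpt of 1.15 ± 0.29 and 1.32 ± 0.29 (adjusted p = 0.254 at 6 hr), none of which passed the test. Of the 27 gene lists, camera called 0 at 1 and 3 hr, and 1 at 6 hr, the interferon response list, where 0 of 22 genes were called by limma (camera adjusted p = 0.0243, adjusted p = 0.548 with an estimated correlation, fry adjusted p = 0.642). The Cnn1 call was lost at both times with an offset of 1, where the difference was larger (2.98 at 3 hr and 2.46 at 6 hr, adjusted p = 0.264 and 0.254). A variance model with trend and robust options left the difference at 1.58 and 1.70 but lost the call (adjusted p = 0.891 and 0.138). The call was also lost with only the arrays of the groups compared, and with a stricter filter that left the gene untested. At 3 hr the call was also lost with an offset of 100 (difference 0.84, adjusted p = 0.127) and with all probe sets tested (adjusted p = 0.0583). It was lost there in 8 of 12 fits without 1 array (adjusted p = 0.0624 to 0.121), namely without replicate 2 or 3 of the control neurons at 0 hr, 1 or 3 of those at 3 hr, and 2 or 3 of the Npas4 RNAi neurons at 0 hr or at 3 hr. At 6 hr it was kept in all 12 such fits (highest adjusted p = 0.046).

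Genes that responded to KCl in the mean of both hairpins were then compared between hairpins, and p-values were also adjusted over the 10 tests of this kind. Npas4, the target of the hairpin, was a member of the rising sets and was not left out. The 28 genes that rose at 1 hr had a median hairpin difference of -0.30 at 1 hr, with 24 of 28 lower, and of -0.35 already at 0 hr. For this set camera gave p = 1.73e-09 (adjusted p = 8.65e-09), and with an estimated correlation p = 0.00831 (adjusted p = 0.0415). The 84 genes that rose at 3 hr had a median of -0.15 at that time, with 59 lower, and of -0.26 without replicate 3 of the control neurons at 3 hr. Camera gave p = 6.18e-06 (adjusted p = 1.54e-05), and with an estimated correlation p = 0.0892 (adjusted p = 0.178). The 170 genes that rose at 6 hr had a median of -0.14, with 110 lower, and of -0.055 without replicate 3 of the Npas4 RNAi neurons at 6 hr. Their camera p was 6.84e-05 (adjusted p = 0.000137), and with an estimated correlation p = 0.152 (adjusted p = 0.253). The 211 genes that fell at 6 hr had a median of 0.24, with 153 higher, and of -0.03 at 0 hr. This set had a camera p of 6.92e-09 (adjusted p = 2.31e-08), and with an estimated correlation p = 0.0349 (adjusted p = 0.116). The 19 genes that fell at 3 hr had a median of 0.14 (camera adjusted p = 0.33). Leaving out 1 of the compared arrays gave medians of -0.10 to 0.30, so that its direction is open. The median of 0.30 came without replicate 3 of the control neurons at 3 hr (camera p of 0.00762). The 2 genes that fell at 1 hr were too few for a test.

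The change in response was tested in the same sets, a test that was added after the data had been seen. The 211 genes that fell at 6 hr fell by a median of 1.33 with the control hairpin and by 1.05 with the Npas4 hairpin, a median difference of 0.30 with 178 of 211 genes above 0. Camera gave this difference p = 2.71e-18 (adjusted p = 2.71e-17), and with an estimated correlation p = 0.00313 (adjusted p = 0.0313). None of the 211 was called on its own by limma. With the control hairpin the actin 3' to 5' ratio was between 1.20 and 1.27 at 0 hr and between 1.15 and 1.17 at 6 hr. With the Npas4 hairpin it was between 1.17 and 1.22 at 0 hr and between 1.18 and 1.20 at 6 hr. The Gapdh ratio was 0.682 to 0.729 at 0 hr and 0.704 to 0.733 at 6 hr with the control hairpin. With the Npas4 hairpin the Gapdh ratio was 0.733 to 0.759 at 0 hr and 0.774 to 0.798 at 6 hr. The 170 genes that rose at 6 hr rose by medians of 1.41 and 1.36, a median difference of -0.067 (camera adjusted p = 0.0134, and adjusted p = 0.402 with an estimated correlation). The median difference was -0.11 in the 84 genes that rose at 3 hr (camera adjusted p = 0.00188, and adjusted p = 0.301 with an estimated correlation). It was 0.13 in the 19 that fell at 3 hr (camera adjusted p = 0.0399, and adjusted p = 0.139 with an estimated correlation) and 0.10 in the 28 that rose at 1 hr (camera adjusted p = 0.27). Without replicate 2 of the Npas4 RNAi neurons at 0 hr the median turned to -0.074 for genes falling at 3 hr and to 0.027 for those rising at 6 hr, and without replicate 3 of those at 6 hr the latter turned to 0.019. The difference of genes falling at 3 hr was lost (camera p of 0.0635 to 0.4003) without replicate 2 or 3 of the Npas4 RNAi neurons at 0 hr, any 1 of those at 3 hr, or replicate 1 of the control neurons at 3 hr. That of genes rising at 6 hr was lost (camera p of 0.0577 to 0.498) without replicate 1 or 2 of the Npas4 RNAi neurons at 0 hr, 3 of those at 6 hr, or 3 of the control neurons at 0 hr or 2 at 6 hr. For genes rising at 3 hr it was lost (camera p of 0.0683 to 0.413) without replicate 1 or 2 of the Npas4 RNAi neurons at 0 hr, 3 of those at 3 hr, or 2 of the control neurons at 3 hr. For genes rising at 1 hr the median turned to -0.0039 without replicate 3 of the Npas4 RNAi neurons at 0 hr (camera p of 0.0173) and to -0.063 without replicate 1 of the control neurons at 0 hr (camera p of 0.0193).

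**Figure D4:**
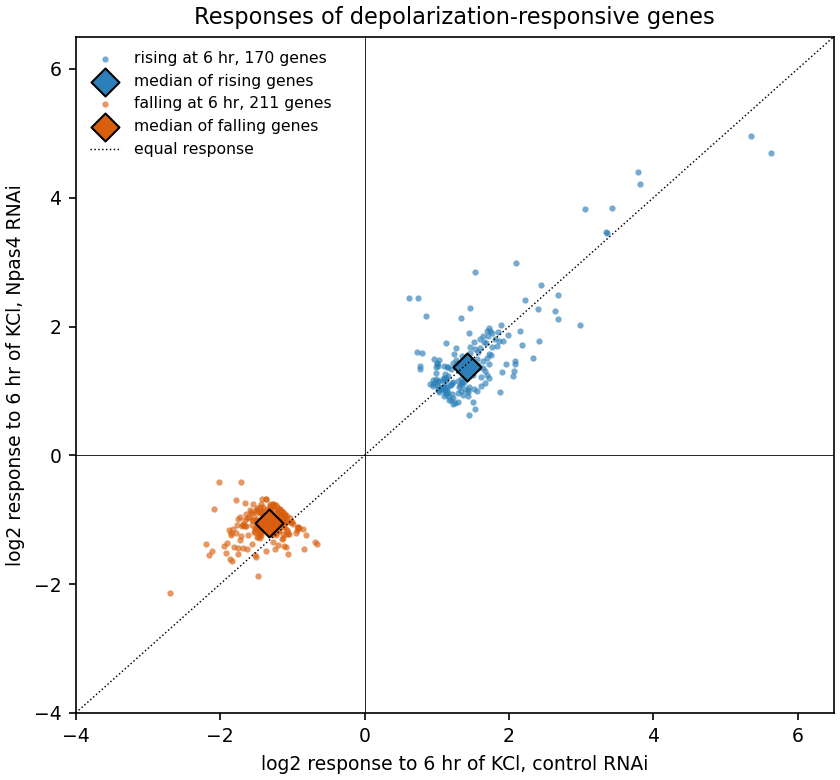
Log2 response to 6 hr of KCl with the Npas4 hairpin against that with the control hairpin, with a point for each of the 170 rising and 211 falling genes, diamonds at the medians and a dotted line for equal responses. The falling genes had medians of -1.33 and -1.05 and the rising genes of 1.41 and 1.36.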

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

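Of the tests in this part, the one for a weaker overall response was chosen after the result was seen, and the test of a difference in response within responsive genes was itself added after the data had been seen. The 211 genes that fell at 6 hr of KCl fell less with the Npas4 hairpin, which stood out because the responses of the hairpins differed by 0.298 in the median. A response that is weaker throughout was argued against, since the ratio of median responses was higher for rising than for falling genes by 0.171, and by 0.113 to 0.212 with any 1 array left out. Scaling between arrays was argued against as the whole cause by a median of 0.278 after quantile normalization, and low signals by a median of 0.302 in the 83 genes with a mean intensity over 500. Of 200 divisions of the arrays 4 gave a median as far from 0 (real value 0.298, highest other 0.345), but these divisions also exchanged hairpins and so do not test the response alone, and whether chance gave it was left open. Hypotheses that stay open are that reduced Npas4 may affect transcripts that fall with activity, and an effect of the hairpin on other transcripts. RNA quality stays open too. The actin 3' to 5' ratio was lower at 6 hr (1.15 to 1.17) than at 0 hr (1.20 to 1.27) with the control hairpin. It was not lower with the Npas4 hairpin (1.18 to 1.20 and 1.17 to 1.22). The Gapdh ratio showed another pattern. It was 0.704 to 0.733 at 6 hr and 0.682 to 0.729 at 0 hr with the control hairpin. With the Npas4 hairpin it was 0.774 to 0.798 at 6 hr and 0.733 to 0.759 at 0 hr.

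Cnn1 stood out because its response differed between hairpins in the interaction test, by 1.58 at 3 hr and 1.70 at 6 hr. The number of genes with a different response was 0 by limma at 1 hr, which all 100 splits of the arrays must reach (highest other 1). It was 1 at 3 hr, where 10 of 100 splits gave as many (highest other 545), and 1 at 6 hr, where 19 of 100 did so (highest other 2829). The splits with 545 and 2829 genes exchanged arrays between hairpins and so carried the hairpin difference into the response, a structure of the samples. These splits therefore do not test the 3 counts, and whether chance gave them was left open. The 84 genes that rose at 3 hr had a median difference in response of -0.113, and of -0.176 to -0.015 with any 1 array left out. The 19 genes that fell at 3 hr had a median difference of 0.135, and of -0.074 to 0.35 with any 1 array left out. The 170 genes that rose at 6 hr had a median difference of -0.067, and of -0.098 to 0.027 with any 1 array left out. The interferon response list had a median difference of -0.27 at 6 hr (camera adjusted p = 0.0243, adjusted p = 0.548 with an estimated correlation, fry adjusted p = 0.642).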

How the results depend on the processing

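For the responsive genes, leaving out single arrays was chosen after seeing the data, as were all alternatives for their difference in response. Counts are of called genes, in the order depolarization at 1, 3 and 6 hr, hairpins at 0, 1, 3 and 6 hr and over the mean of the 4 times, and difference in response at 1, 3 and 6 hr. Values as deposited, quantile normalization, no filter, the mean of a gene's probe sets and array weights left all 11 counts within 1.5 times. The genes called changed more than these counts. After quantile normalization 969 of 1178 calls at 3 hr and 3337 of 4147 at 6 hr of KCl held in the same direction. All probe sets gave 86 and 7047 for depolarization at 1 and 6 hr, 7869 for the mean of the 4 times and 0 for the difference at 3 hr, as more features were tested. Only the arrays compared gave 23, 377, 2750, 208, 167, 485, 356, 1, 0 and 0, with fewer arrays behind the spread, and this fit is left out for the mean of the 4 times, where it uses all arrays. A change of at least 1.5-fold, a narrower criterion, left 544, 1959, 444, 390, 576, 569 and 429 for depolarization at 3 and 6 hr and the 5 hairpin contrasts. Cnn1, the call at 3 and 6 hr in the difference in response, was lost with an offset of 1 (0 and 0), with the filter at the 60th percentile, which left it untested (0 and 0), and with trend and robust options (0 and 0), and an offset of 100 gave 0 and 2, where the cause was not tested. The labels do not say whether the replicate numbers pair the arrays, but all 24 arrays correlated best with arrays of their own number. With the replicate number as a block, the counts were 1795 for depolarization at 3 hr, 1856 and 1714 for the hairpins at 0 and 1 hr and 2 and 7 for the difference at 1 and 6 hr (main 1178, 1130, 1045, 0 and 1), and 75, 5061, 2203, 2302, 5459 and 1 for the others, and the cause was not tested. Leaving out single arrays gave 43 to 53, 755 to 983 and 3471 to 3912 for depolarization, 654 to 902, 543 to 878, 857 to 1159, 982 to 1492 and 4303 to 4566 for the hairpins and 0 to 1, 0 to 1 and 1 to 4 for the difference, from fewer arrays.

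For the responsive genes the values are camera p-values. The hairpin effect on genes rising at 1 hr and falling at 6 hr and the difference in response of genes falling at 6 hr kept their side of the threshold under all alternatives as unadjusted p-values, although with an estimated correlation the hairpin effect on genes falling at 6 hr had an adjusted p = 0.116 over the 10 tests. That difference in response ranged from 2.34e-26 to 7.19e-14 without single arrays. With an estimated correlation, rising genes had p = 0.0892 at 3 hr and 0.152 at 6 hr for the hairpin effect, and 0.211 and 0.341 for the difference, and genes falling at 3 hr had 0.0555 for the difference. With fry the difference had 0.353 and 0.575 for rising genes at 3 and 6 hr and 0.067 for genes falling at 3 hr. The replicate block gave 0.0902 for the latter. An offset of 1 gave 0.153, 0.116 and 0.909 for the difference of genes rising at 3 and 6 hr and falling at 3 hr, and an offset of 100 gave 0.00554 for genes rising at 1 hr and left too few genes falling at 3 hr for a value. Without single arrays the difference ranged from 0.0173 to 0.738 for genes rising at 1 hr, from 2.97e-06 to 0.413 for those rising at 3 hr, from 0.000112 to 0.4003 for those falling at 3 hr and from 0.000187 to 0.498 for those rising at 6 hr, and the hairpin effect on genes falling at 3 hr from 0.00762 to 0.525. The direction of the difference turned for genes falling at 3 hr without replicate 2 of the Npas4 RNAi neurons at 0 hr (0.311). For genes rising at 6 hr it turned without the same array (0.498) and without replicate 3 of the Npas4 RNAi neurons at 6 hr (0.228). The cause was not tested for these changes. Of 66 list calls, 6 held with an estimated correlation, 56 with fry and 54 with quantile normalization, which turned the oxidative phosphorylation list at 6 hr of KCl (p = 0.0875, the cause was not tested). Of 598 calls of named genes, 569 held with quantile normalization, 577 with an offset of 1 and 597 with the block, and 4935 of 5580 held without single arrays. With the mean of all probe sets of a gene, Ahr (-0.0284) and Fdft1 (-0.0331) at 3 hr turned direction between hairpins, where probe sets disagreed. Signals near the background, as for Cnn1, limit what the log2 differences of dim genes can show.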

Other observations

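The tests of the induced Npas4 level, of scaling for the differences at 0 hr and of a smaller share of astrocytes were chosen after the results were seen. Further gene lists were tested over 6 hr of KCl with the control hairpin, and not all were called. Of 12 heat shock genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with the chaperone genes Dnajb4 at 1.86 ± 0.11 and Hspa1a at 1.53 ± 0.30 (camera adjusted p = 0.00242, adjusted p = 0.052 with an estimated correlation, and 0.104 after quantile normalization). Dnajb1 fell on the probe set used (-0.60 ± 0.08) and was higher on the other (0.36), so that its direction is open. Of 17 genes of hypoxia and glycolysis 7 rose and 1 fell, or 9 and 1 adjusted over the list alone, with the glucose transporter genes Slc2a1 at 1.17 ± 0.13 and Slc2a3 at 0.68 ± 0.11 (camera adjusted p = 0.00182, adjusted p = 0.052 with an estimated correlation, with the call lost after quantile normalization). Of 14 p53 targets 3 rose, also adjusted over the list alone, with Pmaip1, a proapoptotic gene, at 2.08 ± 0.25 (camera adjusted p = 0.0563, and 0.0216 after quantile normalization). Of 17 ribosomal protein genes 9 rose, or 14 adjusted over the list alone, with a median of 0.24 that was 0.04 after quantile normalization (camera adjusted p = 4.94e-06, adjusted p = 0.164 with an estimated correlation, and 0.125 after quantile normalization). Of 28 genes of oxidative phosphorylation 1 rose and 1 fell, also adjusted over the list alone, and the median of 0.09 turned to -0.09 after quantile normalization (camera adjusted p = 0.0334, adjusted p = 0.359 with an estimated correlation). Of 10 genes of RNA interference 5 fell, also adjusted over the list alone, with Dicer1 at -1.40 ± 0.13 and Xpo5, an exporter of microRNA precursors, at -0.53 ± 0.10 (camera adjusted p = 0.0708). Of 18 neuropeptide and granin genes 4 rose and 4 fell, or 5 and 5 adjusted over the list alone, with the granin gene Scg2 at 1.11 ± 0.13 and Vip at -1.14 ± 0.18 (camera adjusted p = 0.675).

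Several groups held members that went both ways or few that were called. After 6 hr of KCl 5 of 23 genes of the glutamatergic synapse fell and 1 rose, or 6 and 1 adjusted over the list alone, with the receptor genes Grm2 at -1.40 ± 0.33 and Gria4 at -0.81 ± 0.18 (camera adjusted p = 0.674). Of 20 genes of synaptic vesicles 4 fell, or 3 adjusted over the list alone (camera adjusted p = 0.543), and of 14 bHLH-PAS genes, the family of Npas4, 4 fell and 1 rose, also adjusted over the list alone, with Npas1 at -1.16 ± 0.27 (camera adjusted p = 0.875). Of 22 interferon response genes 2 rose and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.211), of 14 cholesterol synthesis genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.13), and limma called 0 of 8 oligodendrocyte and 0 of 12 endothelial and fibroblast markers (camera adjusted p = 0.713 and 0.107). With the Npas4 hairpin, over the mean of the 4 times, 3 of 14 p53 targets were higher, including the cyclin gene Ccng1 (0.76 ± 0.05), and 6 lower, also adjusted over the list alone (camera adjusted p = 0.614). Of 27 ion channel genes 7 were higher and 7 lower, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.843), of 16 GABAergic genes 4 and 4, or 5 and 5 (camera adjusted p = 0.721), and of 17 general neuron markers 8 and 5, or 9 and 5 (camera adjusted p = 0.645), with Tubb3 at 0.42 ± 0.05 and Elavl4 at -0.70 ± 0.08.

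The difference between hairpins was present before KCl. In the 1045 genes called at 1 hr it did not grow with the induced Npas4 level, since the median difference at 6 hr over that at 0 hr was 0.972, and 0.903 to 1.02 with any 1 array left out. The Npas4 hairpin left 16.3% of the control level at 0 hr, a share that is not exact, and 12.8% at 6 hr. A difference that follows this share would also change little, so the ratio does not test whether reduced Npas4 is the cause. Genes chosen at 1 hr leave out differences that appear later, and the 211 genes that fell at 6 hr had a median hairpin difference of -0.03 at 0 hr (5 called higher, 19 lower) and 0.24 at 6 hr (50 and 9). Scaling was argued against as the whole cause because 92.8% of the 1130 genes called at 0 hr were still called after quantile normalization, and different processing of the arrays that carry the MAS5 note because the 2 arrays whose note differs from their hairpin lay at 0.0381 and 0.0203 on a scale from their own hairpin at 0 to the other at 1, within the range of -0.184 to 0.147 of the 22 other arrays. A hypothesis that stays open is that the low level of Npas4 in unstimulated neurons may keep such genes active. It concerns the 553 genes called lower at 0 hr rather than the 577 called higher. An effect of the hairpin on other transcripts stays open too, since the hairpin sequences were not used here. RNA quality was not tested as a cause and stays open. The Gapdh 3' to 5' ratio at 0 hr was 0.733 to 0.759 with the Npas4 hairpin and 0.682 to 0.729 with the control hairpin. The actin ratio did not show this shift, at 1.17 to 1.22 with the Npas4 hairpin and 1.20 to 1.27 with the control hairpin. For the mean of the 4 times, only the real split of 100 gave as many genes (real value 4652, highest other 111). The splits exchanged arrays within each time without regard to replicate number. Chance is therefore argued against only for arrays taken as independent. The labels state 3 independent experiments, and a chance division by experiment was not tested and stays open.

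The 19 cell cycle genes were lower with the Npas4 hairpin at the mean of the 4 times. A smaller share of astrocytes was argued against as the whole cause, because the median of the cell cycle list lay below that of the astrocyte list by -0.618, and by -0.639 to -0.573 with any 1 array left out. Fabp7 (0.03 ± 0.04) and Vim (0.08 ± 0.03) were not called. Their mean intensities of 21909 and 18430 with the control hairpin lay toward the top of the arrays' range. Other glia were not covered by this comparison. The astrocyte markers Aldh1l1 (-0.48 ± 0.05), Slc1a3 (-0.24 ± 0.06), Tnc (-0.21 ± 0.06) and Hes5 (-0.31 ± 0.10) were lower, so that a part from fewer astrocytes stays open. Scaling was argued against as the whole cause by a median of -0.549 after quantile normalization. Fewer dividing cells, of whatever type, could account for the difference, and this remains a hypothesis that was not tested.

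A hypothesis for Cnn1 was a shared change of cytoskeletal and smooth muscle genes regulated by SRF, tested with 21 genes written down after the Cnn1 result was seen. Their median difference in response at 6 hr was 0.0491, with 13 of 21 above 0 and 0 called by limma. This argues against it.

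For the 7 comparisons of 3 against 3 arrays, the 10 splits of the 6 arrays are too few for a share under 0.05. The real split was the only 1 with as many genes in each, with 53, 1178 and 4147 genes after 1, 3 and 6 hr of KCl and 1130, 1045, 1483 and 1582 between hairpins at 0, 1, 3 and 6 hr. The highest other split called 1 gene for 6 hr of KCl and 0 genes by limma in the other 6 comparisons.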
